A study of Homo sapiens with 8 samples.

How the data were processed

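MicroRNA levels were measured in MM.1S cells with TaqMan low-density array cards, which run 1 quantitative PCR assay per well. Per the labels' protocols, total RNA from cell pellets was reverse transcribed with stem-loop primers in a multiplexed reaction, amplified before the array and then quantified. Each card has 384 wells, of which 377 hold miRNA assays and 7 controls, including 4 wells of U6 and the plant assay ath-miR159a. Cards A and B hold different assays and were joined as 1 panel of 754 miRNA assays, of which 746 carry human names. 4 conditions were run once on each card, so 8 cards were read and no comparison has replicates. The stromal cells came from patients, per the labels, and nothing about donors was used.

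The authors deposited 3 tables. The first holds raw Ct values in cycles per the file headers, including wells above 37. The second holds dCt, the Ct of a miRNA minus that of a control RNA, which per the file headers is in cycles, that is log2 steps with higher values for less RNA. The third holds the authors' fold changes as a linear ratio, 2 to the power of minus ddCt, per the file headers. For some miRNAs undetected in the control, the value is instead 2 to the power of minus dCt of the test sample alone. Examples in co-culture are miR-214 (log2 value -12.88) and miR-127-3p (-13.62). Such miRNAs read as lowered there, though they were detected only in the test sample. The design text states a Ct limit of 37 and normalization to the mean of RNU44 and RNU48. The deposited dCt and fold changes subtract a single control instead, the same for all values of a column and card except that of miR-572 in control media. For the fold changes on card A it was U6 for the drug alone and RNU48 for the other comparisons. On card B it was RNU44 for the drug alone, U6 for co-culture and RNU48 for the drug in co-culture. In the dCt table the control differs between columns of one card, so columns of that table are not on one reference. The deposited dCt table holds 259 miRNAs, those whose lowest Ct was at most 30.97, and leaves out 157 miRNAs with Ct of 37 or less in some sample. The version of the ddCt program is not given in the sources used here.

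The tables number their samples 1 to 4. These were set against the labels by role, from the ratios in the fold change header and the labels' descriptions as control, control and test, or test. Samples 1 and 2 follow from the descriptions. Samples 3 and 4 rest on the assumption that each drug sample was divided by the control of its own culture, and no value was used to assign them. The values speak against an exchange of samples 3 and 4: of 19 stromal or DLK1-DIO3 list miRNAs at least 4-fold higher in sample 2 than in sample 1, 15 were at least 4-fold higher in sample 4 than in sample 3, and 0 the other way round, with undetected wells set at 37.

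From the raw Ct values, dCt was computed as Ct minus the mean of RNU44 and RNU48 on the same card, with Ct above 37 taken as not detected. The log2 fold change is minus ddCt, and miRNAs past 2-fold, 1 cycle, were counted. A miRNA detected in 1 of 2 samples was given a bound by setting the other at 37. The pooled SD of the U6 wells is 0.16 cycles, from 0.07 to 0.24 per card and condition, and is taken as the error of a well. No p-value was computed. The 12 miRNA lists and the set of passenger strands, whose names end in an asterisk, were fixed before the data were examined. Each list's median was set against 10000 random lists of the same size, drawn with replacement from other miRNAs of the same card and Ct quartile. Lists with fewer than 5 measured members were given values only.

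The miRNAs named are, per comparison, the 10 most raised and 10 most lowered with Ct up to 32 in both samples and 2-fold in the same direction under both the RNU and the median-miRNA normalization. Added to these are up to 4 per direction detected at Ct up to 32 in 1 sample only, up to 4 per list, the control RNAs and the plant assay. Guide strands, list members above Ct 32 and miRNAs higher or lower in both co-cultures were named in addition, after their values were seen.

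On simulated cards with well noise of the measured size, for the drug alone comparison with 253 miRNAs, 57 of 57 miRNAs changed by a log2 value of 3 downward and 44 of 47 by 1.5 downward passed 2-fold, and 0 of 53 unchanged ones did. That noise is from U6 wells, with mean Ct from 13.5 to 15.1, and wells that drop out were not simulated. The simulation checks the computation and does not show how well changes are found at higher Ct. Alternatives fixed before the data were examined were RNU44 alone, RNU48 alone, U6, the median of detected miRNAs, the controls of both cards together, Ct limits of 35 and 32, undetected wells set to 37, and the deposited dCt table. The authors' fold changes, the median of the shifts on each card and subsets for the correlation were added after the data were seen. Gene neighbourhoods came from a RefSeq table of assembly GRCh38.p14, used only to find neighbouring miRNA genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.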

Results

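MicroRNAs were measured by quantitative PCR in MM.1S cells, a human multiple myeloma cell line, in 4 conditions. The cells were kept for 8 h in control media, with the kinase inhibitor RGB-286638 at 50 nM, in co-culture with bone marrow stromal cells, or in that co-culture with the drug. Each condition was run once on each of 2 array cards, A and B, which hold different assays. There are no replicates, so no p-value is given, and every change below describes these cultures only. The 754 miRNA assays gave a quantification cycle (Ct, lower for more RNA) of 37 or less for 337 miRNAs in control media, 363 in co-culture, 312 with the drug and 339 in co-culture with the drug. The plant assay ath-miR159a gave no signal in any of 8 wells. The tables number their samples instead of naming them. The drug columns were identified on the assumption that each drug sample was divided by the control of its own culture, and the stromal miRNAs below lie as this assumption has it.

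Repeated wells of the control RNA U6 had a pooled SD of 0.16 cycles, which corresponds to an error of 0.28 for a log2 fold change. The threshold of 2-fold, 1 cycle, is 3.56 times that error. This is an error of wells at high abundance, not of cultures, and the scaled median deviation of the drug effect in MM.1S alone rose from 0.23 for mean Ct up to 24 to 1.36 for Ct between 32 and 37. Control RNAs also moved. In co-culture with the drug, RNU44 on card A came up 0.85 cycles later than in co-culture without it, RNU48 0.51 and U6 1.14 cycles later.

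**Figure D1:**
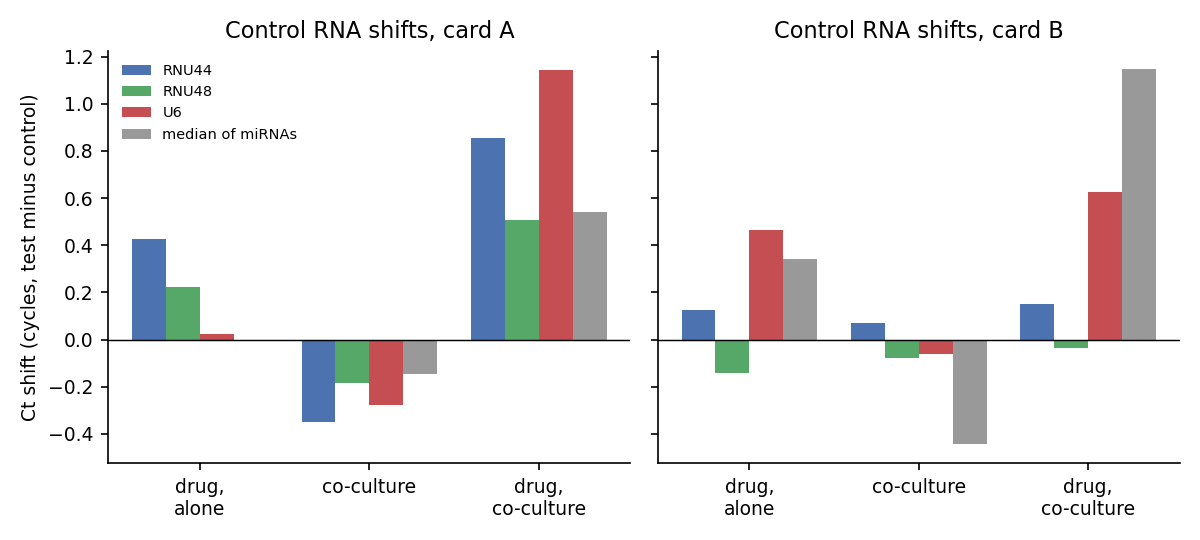
Shift in Ct (cycles, test minus control) of RNU44, RNU48, the mean of the U6 wells and the median of the miRNAs detected in all 4 samples, for each comparison and card. On card B the miRNA median moved by 1.15 cycles after the drug in co-culture, while RNU48 moved by -0.04.

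The first comparison asks what RGB-286638 changed in MM.1S cells alone. miR-215, a miRNA known to be raised through p53, rose 15.9-fold, from Ct 30.20 to 26.54. miR-886-5p, a fragment of a vault-like non-coding RNA, rose 4.43-fold, while miR-886-3p from the same RNA had a log2 fold change of 0.19. Passenger strands are the less abundant strands of their hairpins, taken here as those named with an asterisk. They were low after the drug: miR-92a-1* fell 22.6-fold, miR-30d* 6.60-fold, miR-16-1* 5.05-fold, miR-15a* 3.49-fold and miR-19b-1* 3.37-fold. miR-222* was found at Ct 28.02 in control media and not with the drug, at least 507-fold lower.

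Of 290 miRNAs measured in both samples, 23 were raised and 42 lowered by 2-fold or more, and 16 and 34 were so under normalization to the median miRNA as well. The median log2 fold change was 0.27 on card A and -0.41 on card B, and 35 of the 42 lowered miRNAs were on card B. At Ct up to 32 in both samples 11 were raised and 15 lowered. Those raised under the median normalization as well were miR-215, miR-886-5p, miR-885-5p (3.02-fold), miR-23b (2.63-fold) and miR-1233 (2.09-fold). Also lowered under both were miR-149 (6.31-fold), miR-1254 (4.25-fold), miR-139-5p (2.69-fold), miR-629 on card B (2.63-fold) and miR-148a* (2.60-fold). A further assay of miR-629, on card A, had a log2 fold change of 0.22. miR-26a-2* was at least 89.4-fold lower and miR-19a* at least 39.9-fold lower, as neither was detected with the drug. miR-23a was also undetected with the drug, at least 52.8-fold lower, but it was undetected in co-culture too.

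Passenger strands had a median log2 fold change of -0.96 against -0.14 for the other miRNAs of card B, which held all the passenger strands that were measured. 23 of 47 passenger strands and 12 of 69 others fell by 2-fold or more, 18 and 9 under the median normalization. Random lists from the same card and Ct quartile had medians from -0.33 to -0.01 (central 95%), and none of 10000 was as low.

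In the miR-17-92 family, known targets of MYC and E2F, 4 of 20 measured members fell and none rose, 3 under the median normalization as well. miR-92a-1*, miR-19b-1* and miR-17* (log2 fold change -1.30, and -0.95 under the median normalization) were among them, while the guide strands miR-92a and miR-19b had values of 0.11 and 0.61. Among the miR-15/16 family, repressors of cyclins and BCL2, 4 of 9 fell and 1 rose: miR-16-1*, miR-15a* and miR-15b* (-1.16, and -0.81 under the median normalization, which left 3 lowered) fell, and the guide miR-16 had a value of 0.93. Of the 9 measured p53-responsive miRNAs only miR-215 passed 2-fold. miR-194 stood at 0.77, miR-192 at 0.41, miR-34a at 0.37, miR-34a* at -0.43, and the assays of miR-34b at -0.44 and 0.30.

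All 7 measured haematopoietic miRNAs stayed within 2-fold (miR-146a 0.44, miR-150 0.39, miR-142-3p 0.38, miR-223 0.28). In the let-7 family 2 of 10 fell, and the members with Ct up to 32 stayed within 2-fold (let-7g 0.66, let-7c 0.41, miR-98 -0.33, let-7e 0.23). Of the miR-29 and miR-30 families 1 of 11 fell, miR-30d*, with miR-30e-3p at -0.46, miR-29a* at 0.42 and miR-30b at 0.31. Of 13 inflammatory and stress miRNAs 1 rose, and miR-181c stood at 0.52, miR-146b-5p at 0.47 and miR-132 at 0.40. Of 6 epithelial miRNAs 1 rose (miR-429, 2.84-fold, at Ct 32.66 in control media), and miR-200b stood at -0.51, miR-375 at 0.33, miR-200c at 0.24 and miR-141 at 0.21. Of 18 stromal miRNAs 2 rose and 2 fell, with miR-23b the only one past 2-fold at Ct up to 32 (miR-708 0.55, miR-218 0.50, miR-22* -0.55). The DLK1-DIO3 list had 3 measured members, none past 2-fold (miR-494 -0.16), and the placental C19MC list 2 (miR-519a -0.34, miR-520c-3p -0.29).

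The second comparison asks what the stromal cells changed. miRNAs typical of stromal cells appeared in co-culture: miR-214, undetected in control media, reached Ct 27.12, at least 782-fold higher. miR-145 was 514-fold and miR-31 359-fold higher, miR-143 at least 428-fold, and miR-199a-3p 59.5-fold higher. miR-127-3p, of the imprinted DLK1-DIO3 cluster that mesenchymal cells express, was at least 467-fold higher. The haematopoietic miRNAs measured in both samples stayed within 2-fold, 7 of 7, with miR-223 at -0.33, miR-142-5p at -0.30 and miR-150 at -0.26. A further member of that list, miR-363, was detected only in the co-cultures (Ct 34.67 without the drug), at least 4.18-fold higher without the drug and 4.58-fold with it.

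24 miRNAs were at least 4-fold higher in both co-cultures than in the matching cultures without stromal cells. Of these, 7 were on the stromal list and 8 on the DLK1-DIO3 list, against 2.86 on either list for 24 drawn from the 311 miRNAs detected in both co-cultures. miR-376a (at least 178-fold without the drug), miR-376c (at least 141-fold) and miR-411 (at least 129-fold) were among the DLK1-DIO3 members. On neither list were miR-224 (at least 183-fold), miR-125a-5p (136-fold), miR-99b (at least 88.5-fold) and miR-126, an endothelial miRNA (at least 22.0-fold). Stromal-list members that MM.1S already held at Ct 28 or lower moved less: over 10 such members of both lists the median was -0.21 and the highest 0.74, that of miR-100. Counting single comparisons without the drug, 3 of 19 measured stromal miRNAs rose, 6 more were detected only in co-culture and 2 only in control media. Of 4 measured DLK1-DIO3 miRNAs 1 rose (miR-323-3p, 1.30) and 2 fell (miR-758 -3.74, miR-136 -1.82), and 12 more were detected only in co-culture and 3 only in control media. 4 miRNAs were at least 4-fold lower in both co-cultures: miR-135b, miR-429, miR-758 and miR-191*, named after their values were seen.

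**Figure D2:**
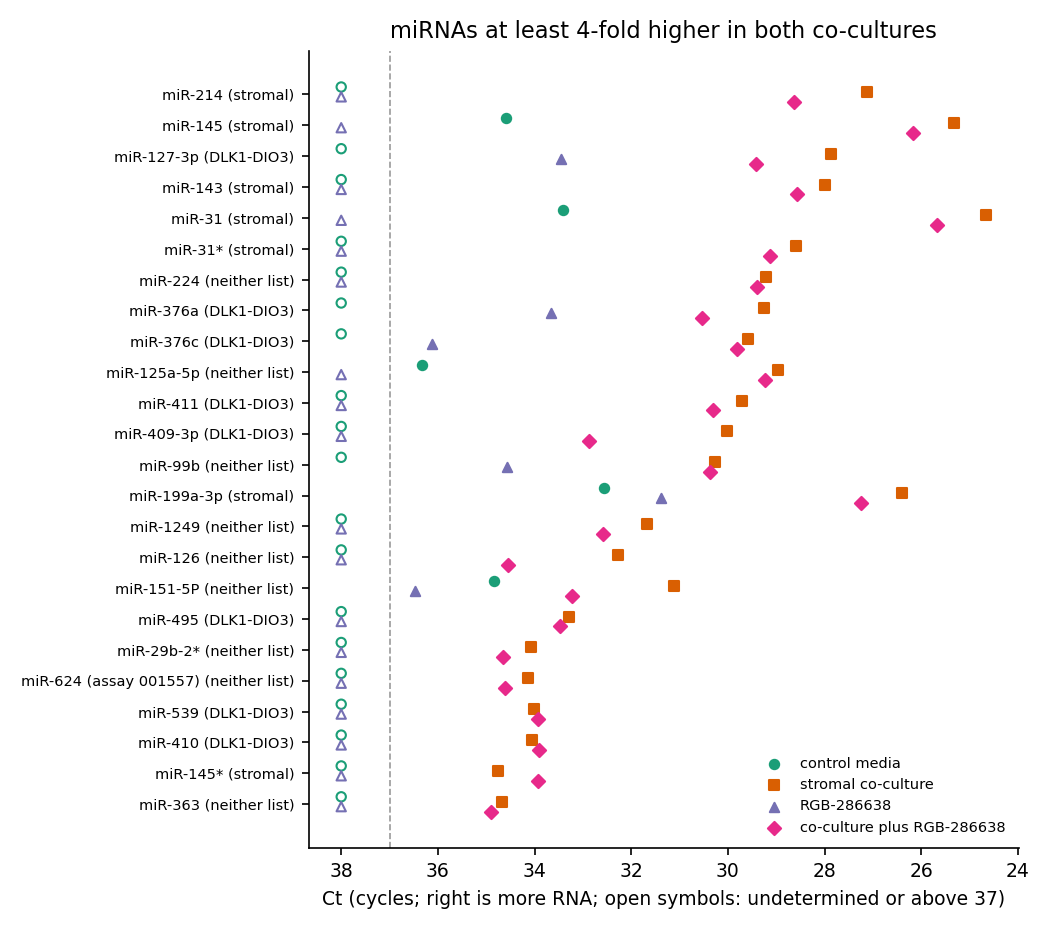
Ct (cycles, axis reversed so that more RNA is to the right) of the 24 miRNAs at least 4-fold higher in both co-cultures, one symbol per condition, with the list of each miRNA in brackets. Open symbols stand for wells undetermined or above 37. miR-214 lies at 27.12 and 28.63 in the co-cultures and was undetected without stromal cells.

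Of 307 miRNAs measured in both samples, 28 were raised and 19 lowered by 2-fold or more, 20 and 18 under the median normalization as well. The median log2 fold change was -0.14 on card A and 0.29 on card B. At Ct up to 32 in both samples and under both normalizations, miR-148a* (6.34-fold), miR-1227 (2.83-fold) and miR-885-5p (2.05-fold) were raised, and miR-502-5p (2.57-fold) and miR-378 (2.31-fold) lowered. Another assay of miR-378, at Ct 24.43 in co-culture, stood at 0.61. miR-15a was detected only in the co-culture without the drug (Ct 27.35, at least 666-fold higher) and in no other sample. That bound rests on a single well. miR-15a*, of the same hairpin, was detected in all 4 samples, at Ct 26.97 in control media and 26.94 in co-culture. miR-23a (at least 79.6-fold), miR-451 (at least 49.1-fold), miR-450b-5p (at least 40.6-fold) and miR-202 (at least 40.2-fold) were detected in control media and not in co-culture. Of these, miR-23a, miR-202 and miR-451, an erythroid miRNA, were detected again in co-culture with the drug, and miR-202 also with the drug alone.

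Of the other lists, 1 of 21 miR-17-92 members rose (miR-106b*, 1.38, and 0.94 under the median normalization), with miR-19a* at 0.85, miR-19b-1* at 0.66 and miR-18b at 0.58. Of 10 p53-responsive miRNAs 1 rose, miR-145, which is also on the stromal list. The median of this list, -0.28, was below the range of random lists (-0.24 to 0.44, percentile 1.39, and 3.51 under the median normalization), and miR-215 stood at -0.71, miR-107 at -0.66 and miR-34c-5p at -0.45. In the let-7 family 2 of 11 rose, neither of them by 2-fold under the median normalization, while let-7c stood at -0.55, miR-98 at -0.55 and let-7a at -0.41. In the miR-15/16 family 1 of 9 rose, and miR-503 stood at 0.78. Of the miR-29 and miR-30 families 1 of 12 rose, with miR-30d* at 0.76. Of 15 inflammatory miRNAs 2 rose, with miR-125a-5p the most raised, miR-221 at 0.76 and miR-9 at -0.51. Of 6 epithelial miRNAs 1 fell (miR-429, -2.90). The erythroid, endothelial and platelet list had 1 member measured in both samples, miR-126* at -3.10, and none was measured in both for the drug alone. Of 3 C19MC miRNAs 1 rose (miR-520b, 1.85) and 1 fell (miR-519a, -1.38). Passenger strands had a median of 0.31 against 0.26 for other card B miRNAs.

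The third comparison asks what the drug changed in co-culture. miR-215 rose 23.4-fold, from Ct 30.65 to 26.78, and miR-886-5p 3.04-fold. Passenger strands were low again: miR-148a* fell 20.4-fold, miR-335* 7.83-fold, miR-19b-1* 7.37-fold, miR-16-1* 5.55-fold and miR-25* 4.50-fold. miR-222* was at least 688-fold lower, undetected in both drug samples. The 17 card A miRNAs that were higher in both co-cultures had a median log2 fold change of 0.10, against 0.21 for 95 others of that card with Ct between 24 and 34. They were chosen for being high in co-culture with the drug too. A miRNA that the drug brought down to its level without stromal cells could therefore not be among them.

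Of 311 miRNAs measured in both samples, 18 were raised and 51 lowered by 2-fold or more. Under the median normalization the split turned to 39 raised and 32 lowered, and 16 and 30 passed under both. That normalization left a median log2 fold change of 0.47 on card B. Centring each card on the median of its shifts, added after the data were seen, gave 22 raised and 40 lowered. With RNU44 and RNU48 the card medians were 0.24 on card A and -0.62 on card B. At Ct up to 32 and under both normalizations, miR-489 (3.14-fold), miR-450a (2.48-fold) and miR-378 (2.06-fold, with 0.06 on the log2 scale for its other assay) were also raised. miR-1254 (5.59-fold), miR-636 (2.34-fold) and miR-210, a hypoxia-responsive miRNA (2.14-fold), were also lowered. miR-149 was undetected in co-culture with the drug, at least 621-fold lower. miR-650 (at least 99.8-fold higher) and miR-1225-3P (at least 46.4-fold higher) were detected only in co-culture with the drug, in a single well each, and not with the drug alone. Bounds on miR-30d (at least 9193-fold lower) and miR-15a (at least 500-fold lower) each go with a single well: miR-30d stood at Ct 23.60, 23.78 and 23.55 in the other samples. miR-23a, at least 91.8-fold higher, was undetected in co-culture and with the drug alone and was found at Ct 30.95 in control media and 31.16 in co-culture with the drug.

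Passenger strands had a median of -1.06 against -0.47 for other card B miRNAs. 27 of 50 passenger strands and 17 of 73 others fell by 2-fold or more, 15 and 8 under the median normalization, and none of 10000 matched random lists was as low (central 95% from -0.63 to -0.19). Under the median normalization the passenger median was 0.03 and that of the others 0.62, so the distance between them, -0.59, stayed while the sign of the passenger median did not.

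**Figure D3:**
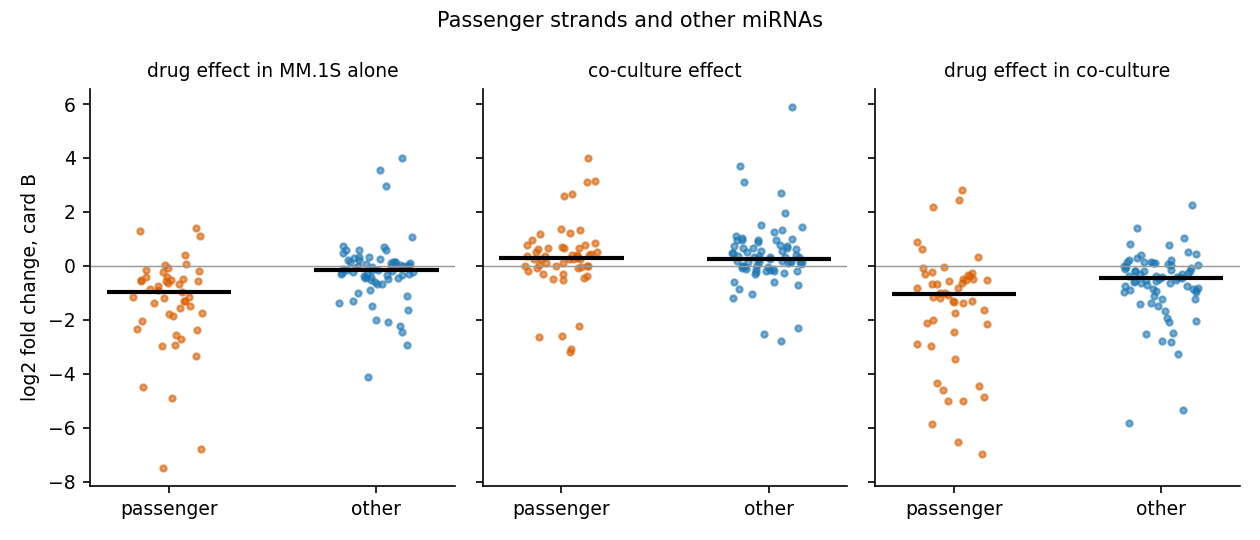
Log2 fold change of each card B miRNA measured in both samples (points) for passenger strands and all others, with the median as a bar, in the 3 comparisons. The passenger median lies at -0.96 and -1.06 in the drug comparisons and at 0.31 in the co-culture comparison.

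The miR-17-92 medians of the drug comparisons, 0.11 alone and -0.04 in co-culture, stood at percentiles of 13.3 and 8.94 of random lists. Under the median normalization the medians were -0.18 and -0.06, well within 2-fold, at percentiles of 0.11 and 0.10. The random lists were matched on card and Ct but not on strand, and the lowered members named here are passenger strands. In this family 6 of 22 fell and none rose in co-culture, among them miR-19b-1*, miR-25*, miR-106b* (-1.20) and miR-20a* (-1.09). Under the median normalization as well 4 fell, with miR-106b* at -0.11 and miR-20a* at 0.00. In the miR-15/16 family 4 of 9 fell, 2 of them under the median normalization as well, with miR-16-1*, miR-15a* (-1.76, and -0.68 under the median normalization) and miR-15b* (-1.37, and -0.28), while miR-16 stood at 0.13. The median of this family was -0.43, at a percentile of 5.86, and -0.28 under the median normalization, at a percentile of 0.63. Of 10 p53-responsive miRNAs miR-215 rose and 1 fell (miR-107, -1.65, at Ct 33.94 with the drug), and miR-194 stood at 0.59, miR-34b at -0.89 and -0.38 in its assays and miR-34a* at -0.53. The first miR-34b value and miR-34a* were 0.19 and 0.56 under the median normalization. All 8 haematopoietic miRNAs stayed within 2-fold (miR-181a 0.55, miR-142-3p 0.47). Of 9 let-7 miRNAs 1 rose, with let-7c at 0.67 and let-7a at 0.65. Of the miR-29 and miR-30 families 1 of 11 fell, with miR-30e-3p at -0.70 and miR-30a-3p at -0.51, which were 0.39 and 0.58 under the median normalization. Of 14 inflammatory miRNAs 2 fell, one of them miR-210, with miR-146b-5p at 0.62 and miR-221 at -0.62. Of 6 epithelial miRNAs 1 rose (miR-429, 1.88), and of 24 stromal miRNAs 1 rose and 1 fell, the fall not under the median normalization (miR-214 -0.83, miR-152 0.65, miR-99a 0.59). Of 13 DLK1-DIO3 miRNAs 3 rose and 2 fell (miR-494 1.12, and 0.98 under the median normalization, miR-127-3p -0.87, miR-376a -0.61). miR-126 fell (-1.60), and the C19MC miRNAs stood at 1.31 (miR-519a) and -1.22 (miR-520c-3p, and -0.13 under the median normalization).

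The last comparison sets the drug effect in co-culture beside that in MM.1S cells alone, which share no sample. Under both normalizations, both effects included the rise of miR-215 and miR-886-5p and the fall of miR-16-1*, miR-19b-1* and miR-1254. The falls of miR-92a-1* and miR-30d* recurred too, but in co-culture their Ct with the drug, 33.50 and 32.40, put them outside the naming rule. Under the median normalization miR-92a-1* stood at -4.15 alone and -5.44 in co-culture, and miR-30d* at -2.37 and -3.91. Across 271 miRNAs, which are not independent replicates, Pearson's r was 0.62 and Spearman's rho 0.44, with r of 0.57 and rho of 0.21 within card A and 0.54 and 0.41 within card B. Over both cards r was 0.55 without the 2 farthest miRNAs, miR-551b* and miR-27a*. With RNU44 and RNU48, 6 miRNAs rose and 20 fell by 2-fold or more in both. All 6 rises were on card A, and 19 of the 20 falls were on card B. Under the median normalization 7 rose and 14 fell, and the share with the same sign went from 70.1% to 57.9%. With RNU44 and RNU48, 4 went opposite ways, none of them among the 210 with Ct up to 32 in all 4 samples. Of those 210, 18 had drug effects that differed by 2-fold or more, 12 lower and 6 higher in co-culture. Under the median normalization 4 were lower and 14 higher, and that normalization left card B at a median of 0.47 for the drug in co-culture. With RNU44 and RNU48 miR-148a* differed most, -4.35 against -1.38, followed by miR-139-5p, 0.24 against -1.43, miR-130a, -0.55 against 1.10, and miR-17*, 0.33 against -1.30. Under the median normalization the differences, co-culture minus alone, were 2.37 for miR-17*, -2.23 for miR-148a*, 2.06 for the assay of miR-378 that was lowered in co-culture, 1.85 for miR-139-5p and -1.46 for miR-130a. miR-148a* was also the miRNA most raised by co-culture among those with Ct up to 32 in both samples, and the co-culture without the drug enters both of its values. The co-culture effect and the drug effect in co-culture share that sample. Their r was -0.31, where well noise alone gave -0.50, with covariances of -0.54 and -0.03. That noise was of the size seen in U6 wells, at high abundance. The scaled median deviation of the co-culture effect rose from 0.17 for mean Ct up to 24 to 1.59 for Ct between 32 and 37. The covariances therefore do not decide whether the relation goes beyond well noise.

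**Figure D4:**
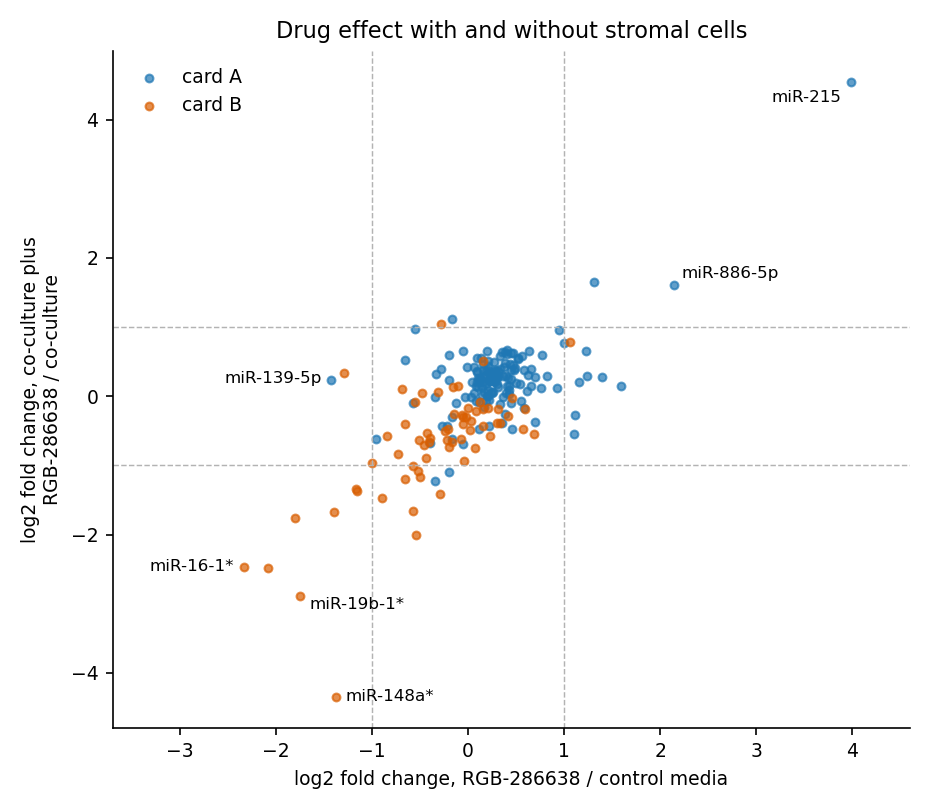
Log2 fold change after RGB-286638 in co-culture against that in MM.1S cells alone for the 210 miRNAs with Ct up to 32 in all 4 samples, coloured by card, with dashed lines at 2-fold. miR-215 lies at 3.99 and 4.55, and miR-16-1* at -2.34 and -2.47.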

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

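All tests of explanations here were chosen after the results were seen. 4 miRNAs had drug effects of 2-fold or more in opposite directions with and without stromal cells, and the difference was not tested. The log2 effect in co-culture minus that alone was -2.69 for miR-10b*, -7.16 for miR-129*, -5.94 for miR-21* and 3.63 for miR-374b*. All 4 are on card B and had Ct above 32 in at least 1 sample. Under the median normalization 4 miRNAs were opposite too, but not the same ones. miR-10b* (-0.21 in co-culture) and miR-374b* (-0.85 alone) no longer were. miR-125b-2* (-1.23 alone, 1.73 in co-culture) and miR-744* (-2.02 and 1.04) were instead.

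Passenger strands were lower than other miRNAs after the drug. The normalization of card B shifts all its miRNAs alike, and the distance within the card was -0.82 alone and -0.59 in co-culture, below all matched random lists. Low abundance as the whole cause is argued against by other card B miRNAs within 1 cycle of each passenger in the control sample (a wider range for 4 of 50 in co-culture). The distance of the passenger median from these was -0.76 alone and -0.55 in co-culture, below all 10000 random lists drawn from them, and -0.45 and -0.58 where that Ct was up to 28. Grouped by mean Ct, the distance was smaller up to 28 (-0.42 and -0.26) than between 28 and 32 (-1.24 and -1.10), and between 32 and 37 it was -1.20 alone and -0.15 in co-culture. The mean Ct includes the drug sample, so a strand that falls moves to a higher group. These grouped values therefore do not decide whether abundance plays a part. Faster turnover of these strands once transcription is inhibited, a biological candidate, may play a part but cannot be told apart. Passengers and guides mostly lie on different cards, and the count of passengers below their guides depends on how the cards are scaled: 38 of 40 pairs alone and 37 of 43 in co-culture with RNU44 and RNU48, 29 and 21 with each card's miRNA median, and 27 and 36 with U6.

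The stromal miRNAs high in both co-cultures may come from RNA of stromal cells in the pellets. 15 of the 24 were on the stromal or DLK1-DIO3 lists fixed beforehand, against 2.86 expected. Expression raised inside MM.1S cells cannot be told apart, because both cell types would be in 1 pellet. List members that MM.1S already held at Ct 28 or lower had a median of -0.21, which does not decide it.

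miR-215 rose after the drug in both cultures. Signal from the near-identical miR-192 is argued against by its log2 changes of 0.41 and 0.26. The choice of normalizer is too, since the lowest values over the normalizers and Ct limits were 3.66 and 4.24, and the deposited dCt table gave 3.01 and 4.38. A general rise of p53-responsive miRNAs of at least 2-fold was not seen: the other members had medians of 0.12 and -0.38, inside the random range, and 0 of 8 and 0 of 9 rose by 2-fold. A smaller p53 response, or one specific to this miRNA, may remain and was not tested, and each value rests on a single well per sample.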

How the results depend on the processing

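The 6 counts of miRNAs past 2-fold stayed within 1.5 times under RNU44 alone, RNU48 alone, both cards' controls together and, added after the data were seen, the median of the shifts on each card. Counts are given as raised and lowered, for the drug alone (23 and 42), co-culture (28 and 19) and the drug in co-culture (18 and 51). With U6, the drug in co-culture gave 52 and 33, and with the median of detected miRNAs 39 and 32. The Ct limit of 35 left 9 lowered in co-culture. The limit of 32, which tests fewer miRNAs, gave 11 and 15, 4 and 2, and 6 and 20. Undetected wells set to 37, which adds miRNAs, gave 41 and 84, 78 and 47, and 45 and 91. The deposited dCt table gave 66 raised for the drug alone, 14 and 4 for co-culture, and 11 and 25 for the drug in co-culture. The authors' deposited fold changes, also added later, gave 7 and 24 for the drug alone, 14 and 15 for co-culture, and 3 and 41 for the drug in co-culture. The last 2 lowered counts include miRNAs that were undetected in the control and whose deposited values read as lowered. Examples are miR-214 in co-culture and miR-650 for the drug in co-culture. The correlation of the drug effects, 0.62, was 0.51 with U6, 0.72 at Ct 32, 0.35 with undetected wells at 37, 0.36 in the deposited dCt table, 0.78 in the authors' deposited fold changes and 0.54 on card B alone.

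In the deposited dCt table, whose control RNA differs between the drug and control columns of card B, the drug effect alone changed sign for miR-16-1* (0.34), miR-1254 (0.59), miR-15a* (0.87), miR-19b-1* (0.92), miR-629 (1.28), miR-148a* (1.30), miR-17* (1.38) and miR-15b* (1.52). Under the median of detected miRNAs, of values past 2-fold the drug effect in co-culture turned for miR-20a* (0.00125) and for the passenger median (0.0324). Values within 2-fold turned as well, among them miR-34b, miR-34a*, miR-30e-3p, miR-30a-3p and miR-29a*. On card B, after the drug in co-culture, the miRNA median moved by 1.15 cycles and the mean of RNU44 and RNU48 by 0.06. Every card B value of that comparison was therefore raised by the same amount. Neither miR-20a* nor the passenger median turned with the median of the shifts on each card. The median of detected miRNAs is the median Ct of each sample, not the median of the shifts. It left card B at a median log2 fold change of 0.47, so part of the gap goes with how it was taken. With RNU44 and RNU48 the card B median was -0.62, and why the references moved apart beyond that part was not tested. Of 134 named values, 91 moved by more than the well error with U6, 74 and in addition miR-20a* with the median of detected miRNAs, and 0 with RNU44 or RNU48 alone. A normalizer shifts all values of a card and comparison alike. With RNU44 or RNU48 alone that shift was at most 0.175, below the error of 0.28, so the 0 was fixed by the references and not by the miRNAs. Some of the miRNAs named for their size still lost their 2-fold change: RNU44 alone kept 4 of 5 in co-culture and 12 of 13 for the drug in co-culture, RNU48 alone 14 of 15 for the drug alone and 12 of 13 for the drug in co-culture, and U6 13 of 15 and 11 of 13. The spread of the log2 changes grew with Ct, and error and real change cannot be told apart in it, which limits what can be said above 32.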

Other observations

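The test of neighbouring genes was written before its result was seen. Outside the naming rule, and picked after their values were seen, miR-27a* came up at Ct 25.99 in control media and 25.72 in co-culture and at 32.79 and 32.75 with the drug, log2 changes of -6.81 and -6.97. miR-551b* changed by -7.48 and -4.60. miR-503 changed by -3.48 and -4.79, while miR-424, its neighbour in the same cluster, had -0.43 in co-culture. Assays that share a name differed: for miR-629 the drug effect alone was -1.39 on card B and 0.22 on card A, and for miR-378 the co-culture effect was -1.21 with one assay and 0.61 with the other.

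Neighbouring miRNA genes may share their drug response. In 70 pairs on the same card within 10 kb, at Ct up to 32, drug effects differed by a median of 0.34 alone and 0.29 in co-culture. Permuted values gave 0.29 and 0.30, and the observed ones stood at percentiles of 85.8 and 43.6 of 1000 permutations, so no likeness of neighbours was seen.

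The control RNA that the deposited fold changes subtract was the one that moved least in 6 of 6 combinations of comparison and card. Why these tables differ from the mean of RNU44 and RNU48 was not tested.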
